A study of Caenorhabditis elegans with 4 samples.

How the data were processed

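Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used on Caenorhabditis elegans hermaphrodites at the L4 larval stage. The worms carried an integrated transgene in which the nuclear hormone receptor NHR-10 is fused to a green fluorescent protein and FLAG tag, together with a copy of unc-119 that rescues the mutant background. Per the labels' protocols, synchronized worms were grown at 20 °C on plates with E. coli HB101, fixed with 2% formaldehyde and sonicated. Per the same protocols, 10% of the cleared supernatant was kept as input, and the rest was precipitated with an affinity-purified anti-GFP antibody. The series holds 4 samples, of which 2 are ChIP replicates and 2 are inputs. Groups and replicate numbers were taken from the sample titles. The description fields do not follow the titles, since they list the antibody under the inputs and only input DNA under the ChIP samples. The labels do not say whether the replicates came from separate cultures, so the spread between them may be partly technical.

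The 3 files used were peak lists, 1 for each ChIP replicate and 1 named as combined. Peaks were called with PeakSeq, per the file headers and the source column of the files, on WormBase WS180 coordinates. PeakSeq scores a ChIP library against a control; which control was used, the PeakSeq version, the aligner, the filters and the way the combined list was made are not given in the sources used here. Each peak carries a q-value deposited by the authors, and no read count, height or fold enrichment stands beside it. The columns of start and end positions are the authors' deposited values as well. Within each list the q-values ran from the smallest to a largest value of 0.000163 in the combined list, 0.000119 in replicate 1 and 0.000122 in replicate 2. The smallest gap between neighbouring peaks was 201 bp in the combined list, 206 bp in replicate 1 and 205 bp in replicate 2. Sequencing depth is unknown, so intervals given below cover only the counting of peaks. Values of the input samples were not used here, and the enrichment of ChIP over control was taken from the authors' calls.

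Peaks were ranked within each list by q-value, with ties broken by width, and q-values were used only to rank or describe peaks or as −log10 q. Peaks were called shared when they overlapped by at least 1 bp; where a peak overlapped several, scores were compared with the one of largest overlap, and the ranks given for the 15 best combined peaks are those of the best-ranked overlapping peak. The overlap of the replicates was tested with a one-sided permutation test against 10000 random placements of the second list, each peak keeping its width and chromosome. Agreement of −log10 q over shared peaks was measured with Spearman's rho and Pearson's r and 100000 permutations; these correlations are across peaks, which are not independent replicates. Shares of peaks are given with 95% Wilson intervals. The number of peaks per chromosome was compared with the chromosome's share of the genome by an exact two-sided binomial test, with Benjamini-Hochberg adjustment over the 6 chromosomes and exact (Clopper-Pearson) intervals. No WS180 chromosome lengths were used; the span of a chromosome was set to the largest peak end on it in any list, giving 99953950 bp in all. The share of peak midpoints in the middle 50% of each span was compared with 50% by the same exact test. Its p-values were adjusted over the pooled autosomes and X, and those of single chromosomes over the 6 chromosomes. These tests treat peaks as independent, and peaks that lie close together were therefore also merged and counted once. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

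The tests were checked on simulated data, in which peaks other than the planted ones were placed or drawn independently of each other, as the tests assume. The rates below therefore check the computation and do not hold for peaks that lie close together, as many here do. Of 100 pairs of unrelated lists, 4% passed the overlap test. With 300 peaks of replicate 1 planted in a random second list, 301.03 were found on average. Of 1000 simulated combined lists with no chromosome effect, 5.4% had any chromosome past the threshold of 0.05, and 86.6% of lists in which X had 1.3 times its weight gave a call on X. The weights were rescaled after that, so the planted ratio of observed to expected peaks on X was below 1.3.

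The gene table used here belongs to another assembly (WBcel235) than the peaks. Its coordinates were not set against the peaks, so no peak was assigned to a gene. For this reason the planned comparisons with gene starts, with fixed gene lists (propionate breakdown, fatty acid metabolism, tissue markers and others), with base composition and with the transgene's own loci were not run. The table was used only for gene identifiers, for the chromosome each gene lies on and for the number of protein-coding genes per chromosome (19971 in all). The rule for the items named, set before the data were examined, took the 15 best-ranked combined peaks, the 10 shared peaks with the best mean rank over both replicates, and 4 genes (nhr-10, unc-119, acdh-1 and nhr-68). The alternatives tried were another overlap rule, the better 50% of each list, lists of equal length, each replicate by itself, combined peaks found in both replicates and gene numbers as background. After the data were seen, merging of neighbouring peaks and leaving out chromosome I were added. The chromosome test on combined peaks in neither replicate and the Fisher's exact test of autosome against X centres were not in the plan either.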

Results

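Binding of the nuclear hormone receptor NHR-10 was mapped by ChIP-seq of an NHR-10::GFP fusion in C. elegans hermaphrodites at the L4 stage, the last larval stage before adulthood. The data comprised 2 ChIP replicates, each with its own peak list, 2 inputs and a combined list. Replicate 1 held 525 peaks and replicate 2 held 593 peaks (mean 559 ± 48.1 SD, n = 2), and the combined list held 1235 peaks. The median peak was 680 bp wide in replicate 1, 715 bp in replicate 2 and 709 bp in the combined list. Peaks covered 0.447% of the chromosome span in replicate 1, 0.529% in replicate 2 and 1.13% in the combined list. In the combined list 372 peaks (30.1%) had a q-value below 1e-10, against 127 (24.2%) in replicate 1 and 156 (26.3%) in replicate 2.

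The first question was where on the chromosomes the peaks with the smallest q-values lay. The series holds no ChIP of another strain or factor, so sites particular to NHR-10 cannot be told apart by this ranking. In the combined list the best-scored region was on chromosome X at 16929210–16931957 (2748 bp, q = 2.31e-229), and it ranked first in both replicates, with q-values of 4.40e-119 and 5.10e-109. The second was on chromosome V at 723844–729720 (5877 bp, q = 8.81e-200), which ranked second in both replicates. The third, also on V at 6220862–6230227, was the widest combined peak at 9366 bp (q = 9.41e-185). It corresponded to separate peaks in replicate 1, of which 6222618–6225815 ranked 6 and 6226021–6229884 ranked 11, and to a peak of rank 4 in replicate 2. Another peak on V, at 6275118–6278816, was at rank 14 of the combined list.

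Chromosome I held 3 of the 15 best combined peaks. The peak at 9379131–9384225 had a q-value of 1.52e-99 and rank 4, the peak at 7079153–7085049 had 3.69e-99 and rank 5, and the peak at 7865971–7868171 had 5.53e-73 and rank 12. The best replicate peaks that overlapped the first of these ranked 27 in replicate 1 and 28 in replicate 2. Chromosome II held 8743101–8748044 (q = 3.11e-88) and 10541954–10549744 (q = 1.70e-84, 7791 bp wide), the latter overlapping peaks that ranked 36 at best in replicate 1 and 39 in replicate 2. Chromosome III held 13462817–13465829 (q = 1.11e-78) and 832791–836226 (q = 3.40e-70). Chromosome X held 4 more of the 15, which were 1503400–1505226 (q = 2.84e-82), 6741044–6744903 (q = 1.33e-74), 17419441–17422002 (q = 2.28e-73) and 6251957–6257172 (q = 8.65e-72). No peak on chromosome IV was among the 15. All coordinates are on WormBase WS180 and counted from 1.

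**Figure D1:**
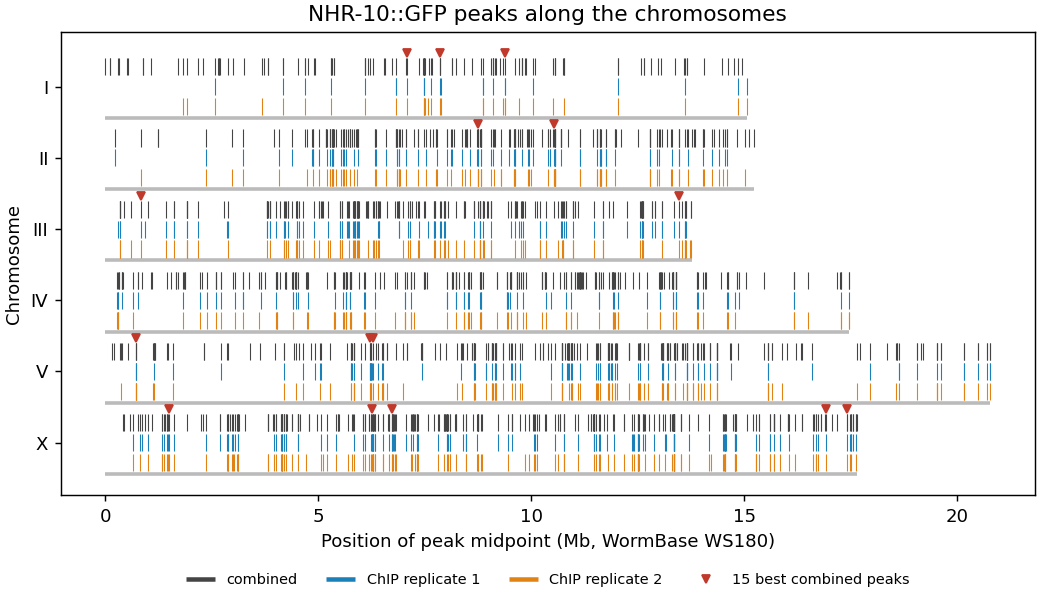
Position of each peak midpoint (Mb, WormBase WS180) on the 6 chromosomes, with 1 row of ticks for each of the 3 lists and a grey line for the span used; triangles mark the 15 best combined peaks. Chromosome I carries visibly fewer ticks in both replicates (24 and 32 peaks) than in the combined list (116 peaks).

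The genes at these regions were not identified here, because the gene table at hand is on another assembly. The transgene itself carries nhr-10 (B0280.8) and unc-119 (M142.1, a neuronally expressed gene used here as the rescue marker), both on chromosome III. Of the other genes looked up, the shunt enzyme gene acdh-1 (C55B7.4), whose product acts in propionate breakdown, is on chromosome I, and nhr-68 (H12C20.3), which encodes another nuclear hormone receptor of the propionate response, is on chromosome V. Whether any of these 4 genes carried a peak was not determined.

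The second comparison asked whether the 2 ChIP libraries found the same regions. Of the replicate 1 peaks, 424 of 525 overlapped a replicate 2 peak (80.8%, 95% Wilson interval 77.2–83.9%), and 424 of the 593 replicate 2 peaks overlapped replicate 1 (71.5%, 67.7–74.99%). Random placement of replicate 2 gave 1.11% of replicate 1 peaks on average and 3.24% at most (one-sided permutation p = 0.0001, the smallest that the placements can give). The share stood at 69.1% when the overlap had to cover at least 50% of both peaks, and at 63.6% when midpoints had to lie within 200 bp.

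Scores of the 424 shared peaks rose together in the 2 libraries. Spearman's rho of −log10 q was 0.74 and Pearson's r was 0.90 (permutation p = 1e-05 for both, the smallest possible). Without the 10 best-ranked shared peaks rho was 0.72 and r was 0.82. The correlation covers only peaks that passed the authors' threshold in both lists. Among the 10 shared peaks with the best mean rank, 9 had a counterpart among the 16 best combined peaks. Of these, 6222618–6225815 and 6226021–6229884 on V had the same counterparts, the combined peak of rank 3 and the replicate 2 peak of rank 4. The 9 included 11887680–11890059 on V, at rank 15 in replicate 1, 6 in replicate 2 and 16 in the combined list. The exception lay near the right end of chromosome I, at 15063995–15067642 in replicate 1 (q = 1.02e-57) and 15064001–15067642 in replicate 2 (q = 8.99e-81). It was at rank 3 in both replicates and overlapped no combined peak.

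**Figure D2:**
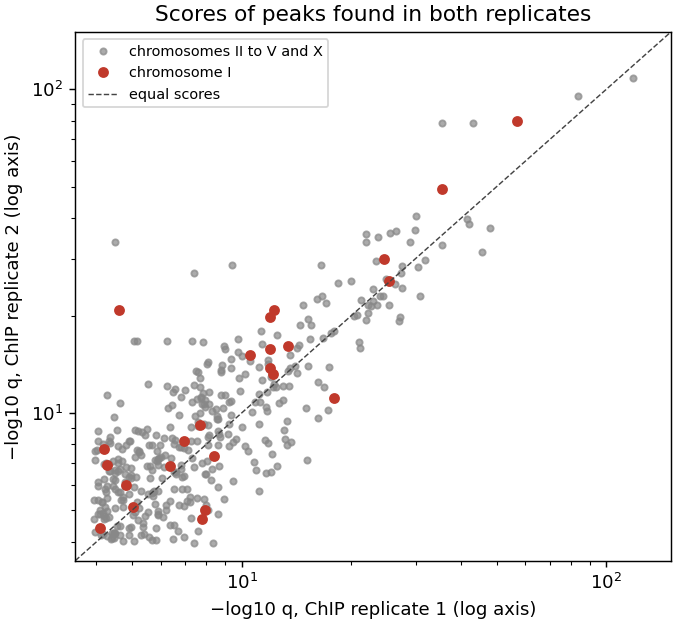
−log10 q of the 424 replicate 1 peaks that overlap a replicate 2 peak, replicate 1 on the x axis and replicate 2 on the y axis, both log axes; the dashed line marks equal scores and red points are peaks on chromosome I. Scores rise together (rho 0.74).

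The third comparison set the combined list against the single libraries. Of the 1235 combined peaks, 402 (32.6%, 95% Wilson interval 29.99–35.2%) overlapped a peak in both replicates, 78 (6.32%) only in replicate 1, 149 (12.1%) only in replicate 2 and 606 (49.1%, 46.3–51.9%) in neither. The share followed the combined rank. Among the best 247 combined peaks, 241 (97.6%) were in both replicates and none was in neither, while among the last 247 none was in both and 231 (93.5%) were in neither. The best combined peak found in neither replicate was at rank 286, on chromosome I at 5315950–5316999 (q = 3.50e-13). Combined peaks found in both replicates had a median width of 1153 bp, and those found in neither had 546 bp. In the other direction, 15 of 525 replicate 1 peaks (2.86%) and 11 of 593 replicate 2 peaks (1.85%) overlapped no combined peak. Apart from the region near the right end of chromosome I, these were at rank 364 or lower.

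**Figure D3:**
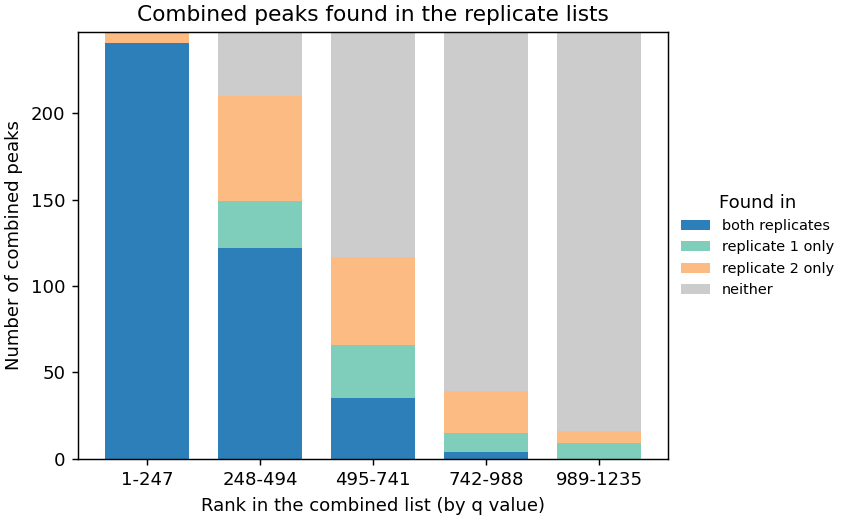
Number of combined peaks (y axis) in 5 groups of 247 by rank in the combined list (x axis), split by whether a replicate list holds an overlapping peak. The share in both replicates falls from 97.6% in the first group to 0% in the last.

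The fourth comparison was the distribution over chromosomes. Chromosome X held more combined peaks than its length predicts, with 277 of 1235 (22.4%) against 17.6% expected, a ratio of 1.27 (95% exact interval 1.14–1.41, exact binomial test, adjusted p = 6.06e-05). Chromosome I held fewer, with 116 peaks (9.39%) against 15.1%, a ratio of 0.623 (0.519–0.740, exact binomial test, adjusted p = 2.64e-08). Both had the same direction and call in each replicate list. On X the ratio was 1.46 in replicate 1 and 1.44 in replicate 2, and on I it was 0.303 and 0.358. The replicate lists held a smaller share of their peaks on I than the combined list, which raises their ratios on the other chromosomes. Ratios without chromosome I were computed for the combined list only. The more extreme ratios of the replicates are therefore not used here as separate evidence for the size of either difference. How much of the higher ratio on X comes from the smaller share on I was not computed. The 606 combined peaks that were in neither replicate gave a ratio of 0.963 (0.784–1.17) on chromosome I and 1.11 (0.937–1.305) on X, and the 402 peaks in both gave 0.330 (0.203–0.503) on I and 1.55 (1.31–1.81) on X. These sets are defined by the replicate lists themselves and follow the combined rank, so their ratios are given without a test of the difference. Chromosome IV stood at 1.26 (1.07–1.46, exact binomial test, adjusted p = 0.0274) among the 606. Of the 116 combined peaks on chromosome I, 28 (24.1%) were in either replicate, against 42.7% on IV to 59.2% on III for the other chromosomes.

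Chromosomes II, III, IV and V did not pass the test in the combined list, with ratios of 0.946 (0.820–1.08), 1.08 (0.941–1.24), 1.07 (0.952–1.21) and 0.966 (0.860–1.08). Chromosome III passed the exact binomial test in replicate 1, at 1.31 (adjusted p = 0.0105), and not in replicate 2, at 1.18 (adjusted p = 0.190). When protein-coding genes per chromosome replaced length as background, X rose to 1.64 (1.47–1.82). On that background, by the same exact test, V, which carries 25.01% of the protein-coding genes, stood at 0.803 (adjusted p = 9.11e-05), II at 0.835 (adjusted p = 0.0112) and IV at 1.14 (adjusted p = 0.0342).

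**Figure D4:**
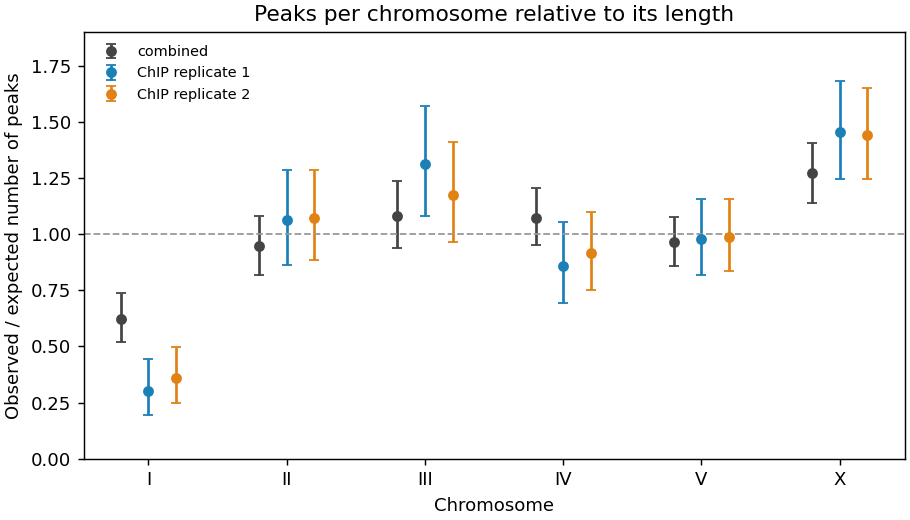
Observed over expected number of peaks (y axis, expected from the chromosome's span) for each chromosome (x axis) in the 3 lists; points are ratios, bars are 95% exact intervals that cover counting only, and the dashed line marks a ratio of 1. X lies above 1 (1.27 to 1.46) and I lies below 1 (0.303 to 0.623) in every list.

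Along the autosomes, combined peaks lay more often in the middle of the chromosome than toward its ends. The middle 50% of the span held 642 of 958 autosomal peaks (67.0%, exact binomial test, adjusted p = 5.68e-26). Every autosome passed the exact test by itself, from 62.1% on I (adjusted p = 0.0142) to 72.2% on V (adjusted p = 1.16e-11). In this organism the autosome arms recombine more and hold fewer essential genes than the centres. On X the middle held 146 of 277 peaks (52.7%, adjusted p = 0.400), and the autosomes and X differed from each other (Fisher's exact test, two-sided p = 1.92e-05). The same contrast stood at 68.7% against 52.6% in replicate 1 (Fisher's exact p = 0.00116) and 69.5% against 51.7% in replicate 2 (Fisher's exact p = 0.000110). These tests count close neighbours separately. With combined peaks within 5000 bp merged, the contrast was 65.0% against 52.8% (Fisher's exact p = 0.00255). Single autosomes were tested in the full combined list only, without merging.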

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

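The overlap of the replicates stayed far above random placement under the 6 other settings tried (63.6% to 83.2%), and rho over shared peaks lay between 0.72 and 0.81 under the 3 others. The share of combined peaks in both replicates moved from 32.6% to 22.7% with reciprocal overlap and 22.1% with midpoints within 200 bp, and was 33.4% in the better 50% of each list. Median widths followed the threshold. They were 997, 935 and 946 bp in the better 50% of the combined, replicate 1 and replicate 2 lists, and 2039, 1354 and 1518 bp in the best 100 peaks of each. The X excess (1.19 to 1.64) and the deficit on I (0.303 to 0.716) kept their direction and call in the better 50% of the list, in each replicate, in combined peaks in both, against gene numbers, with neighbours merged and, for X, without chromosome I. The autosome centre share (1.299 to 1.39 times the 50% expected) did so under these settings except gene numbers, against which it was not run, so gene density along the chromosome was not taken into account. The combined peaks in neither replicate are a different set, in which I (0.963) and X (1.11) did not pass. The ratio on I moved by over 1.5 times in single replicates and in combined peaks in both (0.330). Those settings are short of peaks on I through the low recovery described below. They are therefore no independent check of the deficit on I. Calls absent from the full combined list were III in replicate 1 alone (range over single replicates 1.18 to 1.31) and, against gene numbers, II (0.835), IV (1.14) and V (0.803), besides IV among the peaks in neither replicate (1.26); the cause was not tested. Without chromosome I, a setting chosen after seeing the data and run for these ratios on the combined list only, X was at 1.19 (1.07–1.32). No paired analysis was possible because values of the input samples were not used here, so no comparison with shared replicate numbers could be made. Alternatives that need gene positions or sequence were not run, and without read counts no limit from depth can be given.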

Other observations

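The tests in this part were chosen after the results were seen, except that gene numbers as a background for X were planned before. Combined peaks lay close to each other. Of the 1235 peaks, 612 (49.6%) had a neighbour less than 5000 bp away, and merging such neighbours left 862 groups, of which 239 held more than 1 peak. There were 15 groups of 5 or more peaks, with 4 each on IV, V and X, 2 on III, 1 on II and none on I. The fullest was on X at 13348213–13360056, with 7 combined peaks in 11844 bp, 6 peaks in replicate 1 and 7 in replicate 2, the best at combined rank 89. The next was on V at 13081011–13090799, with 6 combined peaks and 3 in each replicate. A group on II at 10541954–10563799 held 5 combined peaks, among them the peak of rank 7, and 5 and 7 peaks in the replicates. Another on X, at 6736103–6750597, held 5, among them the peak of rank 10.

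The grouping of peaks was set against 2 simple accounts of it, with no other bin size or merge distance tried. If it followed only from peak-rich stretches of 500 kb or more, random placement within 500 kb bins would give a like share. The 2000 such placements gave 17.8% on average and 23.1% at most, against 49.6%. Shorter peak-rich stretches were not tested, because placement within a bin also spreads their peaks apart. If it came only from broad regions that the caller had split at gaps under 1000 bp, merging such peaks would end it. After merging, 34.8% of the 1068 merged peaks still had a neighbour, against 19.6% at most in random placements. Broad regions split at gaps of 1000 to 5000 bp were not tested, because such peaks still count as neighbours. The shorter stretches and the wider gaps therefore stay open. The single lists gave 41.5% and 42.0%, against 9.28% and 9.92% on average in random placements. Whether grouped peaks share a gene, or lie in open chromatin that many factors occupy, may be asked once the peaks are set against genes of their own build and was not tested.

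Chromosome I held a smaller share of the peaks in the single libraries than in the combined list. Peaks were compared within 5 groups of like combined rank. All peaks of the first group were in either replicate, those on I included, so it adds nothing to the odds of being in either. These odds were 0.0245 times those of other chromosomes for a chromosome I peak (95% interval 0.00697–0.0862, permutation within rank groups, adjusted p = 0.0012). The odds of being in both replicates were 0.0715 times those of other chromosomes (0.0202–0.253, same permutation, adjusted p = 0.0012). Both values argue against lower depth of the single libraries as the whole cause, since depth acts on all chromosomes. Scores differed too among strong peaks, meaning those of the first rank group that were matched to 1 peak in each replicate. There the replicates' −log10 q summed to a median of 1.004 times the combined value on the other chromosomes (185 peaks). On I it was 0.74 times (15 peaks, at most 0.86), a difference of -0.27 (permutation p = 0.0001, the smallest possible). A scoring of chromosome I that differs between the replicate and combined lists would give such a difference. Peaks on I were also wider in the replicates, at medians of 1196.5 bp (24 peaks) and 1086.5 bp (32 peaks). Other chromosomes had 628 to 706 bp and 643 to 737 bp. The combined list had 785 bp on I, against 679 to 744.5 bp. Better-ranked peaks were wider in every list, so a loss of weaker peaks on I in the replicates would give such widths. This was not tested. The score ratio by itself does not say whether I was scored too low in the replicates or too high in the combined list, and it is not independent of the low recovery. A candidate cause is the region at 15063995–15067642, close to where this species has its ribosomal RNA gene array: it was at rank 3 in both replicates, ended at the same base in both (as did 4 of the 424 shared pairs, itself included) and was absent from the combined list, so reads there may have entered the chromosome's scaling in the replicates alone. Only 1 chromosome has such a region, so this cannot be told apart from other properties of chromosome I without read counts. No biological explanation was tested, since the design has no second condition.

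The excess on X was set against 3 accounts. It is not only the reverse of the gap on I, since without chromosome I the ratio was 1.19 (1.07–1.32). It is not only due to neighbouring peaks counted separately, since merging within 5000 bp gave 1.29 (1.14–1.46), and X does not carry more protein-coding genes, against which the ratio was 1.64. A scaling per chromosome that acts alike in all lists stays open, because all 3 lists come from 1 caller. Among the strong peaks defined above, the median of replicate scores relative to combined scores was 1.03 on X (62 peaks) and 0.984 elsewhere (138 peaks). These medians differed by 0.046 (permutation p = 0.0215, unadjusted over 6 chromosomes), and by 0.033 (permutation p = 0.0566) once the low values on I were left out. The excess may therefore be a property of NHR-10 binding, of the calling or of neither. The series holds no ChIP of another strain or factor, so these cannot be told apart.

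Of the 15 replicate 1 peaks that overlapped no combined peak, 8 were on chromosome III, which held 95 of the 525 peaks (Fisher's exact test, two-sided, adjusted p = 0.0223 over 12 tests of 6 chromosomes in 2 lists, the only one under 0.05). In replicate 2 it was 2 of 11, with 96 of 593 peaks on III (Fisher's exact test, adjusted p = 0.695), and the difference between the replicates was not tested. A second region found in both replicates and absent from the combined list was on IV, at rank 512 in replicate 1 and 532 in replicate 2. In the comparison of recovery in either replicate at like rank, II (2.01, 1.25–3.21) and III (2.01, 1.26–3.19) stood above the others (adjusted p = 0.0132 for both, permutation); with chromosome I left out neither passed (1.62 and 1.60, adjusted p = 0.111 for both, permutation), and IV stood below, at 0.504 (0.322–0.790, adjusted p = 0.0190, permutation). For recovery in both replicates, II (1.54, adjusted p = 0.308, permutation) and III (1.37, adjusted p = 0.449, permutation) did not pass with chromosome I included, nor did IV without it (0.723, 0.423–1.23, adjusted p = 0.667, permutation).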
